A study of Mus musculus with 6 samples.

How the data were processed

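PolyA RNA from mouse aortic arches was sequenced after TruSeq library preparation, with an RNA integrity number of at least 7.9, per the labels' protocols. There were 3 control and 3 knockout libraries, and the groups were taken from the sample titles. The columns name a group and a library number (S591 to S599) but not which individual sample they belong to, so libraries are called by that number and no pairing was made. The submitters' processing notes list CASAVA 1.8, cutadapt 1.6.1, RSEM 1.16, Bowtie 0.12.7, limma and edgeR and the mouse build NCBIM37, without saying what each was used for. The annotation and any strand setting are not given in the sources used here.

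The deposited values are a normalised signal on a linear scale, 1 value per gene and library, with no 0 among them. Checked on the values themselves, they equal (reads + 0.5) in CPM of a library size scaled by edgeR's TMM factors, the form that limma's voom gives before the logarithm. Whole reads could be recovered from 100% of the values at a tolerance of 0.01, and TMM factors computed from those reads differed from the ones in the deposited values by at most 1.04e-09. One read was worth between 0.0964 and 0.178 CPM. The 14298 genes listed all reach more than 1 CPM in at least 3 libraries (the lowest value of the third-highest library was 1.02), so genes below that level, and the total depth over all genes, were not analysed here. Genes were listed in order of increasing voom p-value for all 14297 steps between neighbouring genes, with a Spearman correlation of 1, which describes the listing and was not used for any test. The design fixed for this work had assumed normalised values, which is what was found, and the recovered reads were used for added count tests.

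Depth over the listed genes ran from 5904504 to 10072495 reads per library, and the most abundant gene, mt-Co1, took 1.42% to 2.60% of the reads. Counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Gene symbols were looked up by Ensembl identifier in a table of another annotation release, and 13828 of the 14298 identifiers matched while 470 did not. Positions are not printed because that annotation uses another build than the one in the processing notes.

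The groups were compared with limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend in the variance, all 6 libraries, genotype as the 1 factor and no other covariate. Genes needed at least 1 CPM in at least 3 libraries, which removed 0 genes. P-values were two-sided and adjusted by the method of Benjamini and Hochberg over all 14298 genes, with a threshold of 0.05. Rbpj was also compared with an exact two-sided permutation test, whose smallest p for 3 against 3 libraries is 0.1.

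Gene lists were written from textbook knowledge before the data were examined, as were the tests, the rule for named genes and the alternatives, apart from those said to be chosen later. There were 26 lists, of which 25 were tested (the list of sex-linked genes only checked the animals' sex). They were compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 25 lists. An estimated correlation (median over the lists 0.40) and the fry test were alternatives. Some members belong to several lists, 7 of those in the adhesion list among them. The camera test with a small preset correlation takes genes as nearly independent, so the p with an estimated correlation is given beside each call. Members were also adjusted over each list alone.

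The genes named were Rbpj, up to 10 genes in each direction that passed the threshold with the groups apart and a mean of at least 5 CPM, filled to 5 per direction by smallest p, then the 2 members of each list with the smallest p (6 for Notch targets and for adhesion molecules), and Cdh5, Vcam1, Icam1, Jag1 and Hes1. Of the genes this rule names, 2 are not reported here. Any other gene is said to be chosen after its values were seen.

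The alternatives were other pseudocounts, filters, scalings, variance models and thresholds, array weights, each library left out in turn, the edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, and, chosen after seeing the data, limma-voom and the fit without S598 and S599. That fit leaves 1 knockout library, S595, which is assumed to vary like the controls. The tests of time of day and glucocorticoids in the closing section were each changed after a first form had been seen, the one to leave out the genes that had shown the pattern and the other to use the SD of the members as its spread. That of endothelial number was changed in the same way, from 4 adhesion genes picked after the data were seen to the whole adhesion list with its spread over libraries, and a test of macrophage number on those 4 genes was dropped because they had shown the pattern. The comparison was tested on simulated counts for 14298 genes in 3 against 3 libraries. Of 100 genes changed 2-fold it recovered 66%, and of 100 changed 4-fold 96%, with 8.02% of its 187 calls false. Camera called the changed list and 0 of 24 unchanged lists. The simulated genes were drawn independently of each other, unlike the real lists with their median estimated correlation of 0.40. The simulation therefore does not show how often camera falsely calls lists of correlated genes. Nor does it show what share of real changes the gene test finds, since it held no variation shared by the genes of a library. In the real data Socs3 and Ccl2 differed 4.24-fold and 4.31-fold between the group means and missed the threshold.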

Results

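Gene expression was measured by sequencing polyA RNA from the aortic arches of atherosclerosis-prone mice that lack apolipoprotein E. All animals carried floxed alleles of Rbpj, the gene of the DNA-binding partner of Notch receptors. The 3 knockout libraries came from mice that also carried Cdh5-CreERT, a tamoxifen-activated recombinase expressed in endothelial cells, and the 3 control libraries from mice without it. Tamoxifen was given for 1 week at an age of 8 weeks, and a high-fat diet followed for 6 weeks. The control animals carried no recombinase, so the groups differ in its presence as well as in the deletion. Over the 14298 genes listed, the control libraries S591, S592 and S594 held 5904504, 7572040 and 7855001 reads, and the knockout libraries S595, S598 and S599 held 6713700, 10072495 and 6181341. Transcripts of all 4 Y-linked genes examined (Ddx3y, Kdm5d, Uty and Eif2s3y) were present in all 6 libraries, as in male animals. No pair of libraries was a duplicate, since the chi-square per degree of freedom between libraries of one group ran from 13.0 to 35.6. Control S591 was nearer knockout S599 (16.0) and knockout S595 (22.1) than control S592 (33.9) and control S594 (35.6) by this measure. Levels below are normalised CPM (read counts scaled by library size), given as mean ± SD with n = 3 per group, and log2 fold changes are knockout minus control on the log2(value + 1) scale, which understates changes of low genes.

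The first question was whether the targeted gene differed in whole-arch RNA. Rbpj (ENSMUSG00000039191) stood at 189 ± 13.2 in the control and 193 ± 21.7 in the knockout arches (n = 3 each). The log2 fold change was 0.03 with a standard error of 0.12 (limma, Benjamini-Hochberg adjusted p = 0.923). Its 95% interval ran from −0.24 to 0.30, that is from 0.844-fold to 1.23-fold. The exact two-sided permutation p was 0.9, where 0.1 is the smallest that 3 against 3 libraries allow. Between 981 and 2043 reads per library lay behind these values. Leaving out control S591 or knockout S599 turned the sign, to −0.03 and −0.05. A gene-level value from whole tissue does not check the deletion, because the recombinase acts in the endothelium alone and the floxed exons are not given in the sources used here. Cdh5, the endothelial cadherin whose promoter drives the recombinase, stood at 132 ± 12.7 and 139 ± 51.1 (log2 fold change 0.02, adjusted p = 0.962), and its sign turned without control S591, control S592 or knockout S599 (−0.02, −0.01 and −0.26).

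The second question was which transcripts differed across the arch. By limma 3 genes passed the test, all of them higher in the knockout arches. Scgb1a1 (ENSMUSG00000024653), the secretoglobin of airway club cells, rose from 2.40 ± 1.17 to 29.0 ± 7.53, a log2 fold change of 3.17. Bpifa1 (ENSMUSG00000027483), a secreted protein of the upper airway epithelium, rose from 1.72 ± 1.48 to 39.5 ± 9.72, a log2 fold change of 4.001. The third was Cyp2a5 (ENSMUSG00000005547), named here after its values were seen, which rose from 0.159 ± 0.0609 to 5.12 ± 0.613. Each of these had an adjusted p of 0.0317 by limma with Benjamini-Hochberg adjustment and was higher in all 3 knockout libraries. The controls held 52 reads of Scgb1a1 in all against 663 in the knockouts, and 38 against 962 of Bpifa1. For Cyp2a5, 2 control reads against 118 gave a depth-adjusted ratio of 53.6 with a 95% counting interval of 14.5 to 448, and the near-identical Cyp2a4 makes its reads uncertain.

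In the opposite direction, limma called 0 of the 14298 genes at an adjusted p of 0.05, while 1710 were lower and 1150 higher at an unadjusted p of 0.05, where 715 in total would be expected with no difference. With 1 library left out, the unadjusted total of 2860 ran from 1582 (without knockout S598) to 3447 (without control S591). The lower genes with the smallest p included a feedback inhibitor, a receptor and chemokines. Socs3, which restrains cytokine receptors, stood at 64.9 ± 5.33 in the control and 15.3 ± 4.70 in the knockout arches (log2 fold change −2.06, adjusted p = 0.0591). The monocyte chemokine Ccl2 stood at 41.7 ± 7.24 and 9.67 ± 2.69 (−2.02, adjusted p = 0.0644), and the neighbouring chemokine gene Ccl7 at 28.0 ± 1.71 and 6.77 ± 2.91 (−1.96, adjusted p = 0.101). The interleukin-4 receptor gene Il4ra stood at 163 ± 45.4 and 48.0 ± 5.71, and the retinol dehydrogenase gene Dhrs9 at 22.5 ± 4.98 and 6.11 ± 0.922 (adjusted p = 0.0644 each). Of the higher genes that missed the threshold, the clock repressor Nr1d2 stood at 86.5 ± 13.4 and 187 ± 15.3 (log2 fold change 1.11, adjusted p = 0.0644). Rhobtb1 stood at 45.2 ± 9.53 and 94.2 ± 7.49, and the progesterone receptor gene Pgr at 3.32 ± 0.224 and 8.41 ± 0.430 (adjusted p = 0.107 each).

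The number of genes passing the threshold of 0.05 depended on single libraries and on the test. Against 3 genes from all 6 libraries, limma called 671 without control S591, 0 without control S592, 2 without control S594, 6 (all lower) without knockout S595, and 0 without either S598 or S599. The edgeR quasi-likelihood test on the recovered reads called 0 (2899 at an unadjusted p of 0.05), limma-voom called 0 (2988), and DESeq2 called 287 higher and 613 lower (2598). In all, 3646 genes had every knockout value on one side of every control value, 1617 higher and 2029 lower, which is 25.5% where chance gives 10%.

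**Figure D1:**
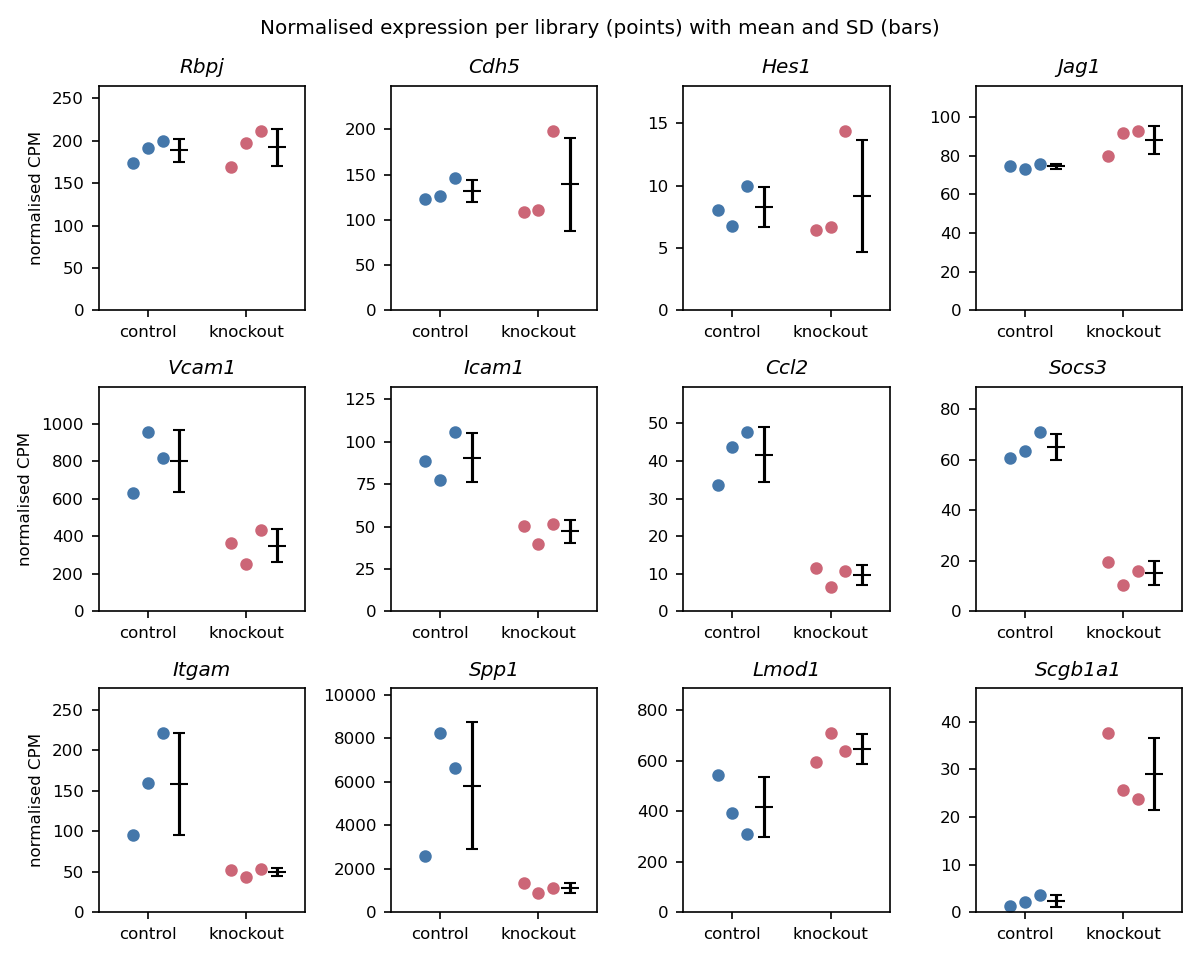
Normalised CPM (vertical axes, linear and starting at 0) of 12 genes in the 3 control (blue) and 3 knockout (red) libraries, each point 1 library, with black bars for the mean and SD. Rbpj overlapped between the groups (189 against 193), while all 3 knockout values of Vcam1, Icam1, Ccl2 and Socs3 lay below all control values and those of Scgb1a1 above.

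The third question was how Notch signalling transcripts stood in whole-arch RNA. The recombinase acts in the endothelium alone, so these values do not show target levels in the cells it acts on. Across the arch, Notch target genes went both ways. Hey2, a Hairy-related repressor, stood at 48.8 ± 9.17 in the control and 84.3 ± 14.6 in the knockout arches, with a log2 fold change of 0.78. The Notch-modifying glycosyltransferase gene Lfng stood at 18.7 ± 5.49 and 10.3 ± 2.27, a log2 fold change of −0.79. The canonical target Hes1 stood at 8.28 ± 1.61 and 9.19 ± 4.51 (log2 fold change 0.06, adjusted p = 0.927), and its sign turned without control S592 (−0.06) or knockout S599 (−0.28). The guidance receptor gene Unc5b (log2 fold change −0.39), the receptor gene Acvrl1 (−0.35) and the arterial connexin gene Gja4 (−0.57) were on the lower side, and Dtx1 (0.54) on the higher side, with adjusted p from 0.168 to 0.306. Of the 17 target genes tested, 1 (Hey2) was higher and 0 lower when adjusted over the list alone, and 0 passed over all genes tested. The list had a median log2 fold change of −0.06 and limma's camera gave an adjusted p of 0.880. That median was 0.19 without knockout S595 and −0.28 without knockout S599.

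Among receptors, ligands and modulators of the pathway, Notch1 stood at 45.6 ± 4.40 in the control and 31.5 ± 2.30 in the knockout arches (log2 fold change −0.52, adjusted p = 0.111). Adam17, the gene of a metalloprotease that cleaves Notch, stood at 112 ± 14.999 and 75.9 ± 11.6 (−0.55, adjusted p = 0.122). The ligand gene Jag1 stood at 74.6 ± 1.42 and 88.2 ± 7.15, with all 3 knockout values above the control values (log2 fold change 0.24, adjusted p = 0.229). Of 19 members tested, 1 (Notch1) was lower when adjusted over the list alone and 0 over all genes. The list median was −0.03, or 0.02 after quantile normalisation, and camera did not call it (adjusted p = 0.565).

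The fourth question, named in the series title, was leukocyte recruitment. Transcripts of leukocyte adhesion molecules and chemokines were lower in the knockout arches. Vcam1, the adhesion molecule that binds monocyte integrins, stood at 800 ± 164 in the control and 351 ± 89.3 in the knockout arches, a 2.28-fold difference of means. Icam1, which binds leukocyte integrins, stood at 90.6 ± 14.2 and 47.1 ± 6.62, a 1.92-fold difference. The selectin ligand gene Selplg stood at 51.5 ± 9.88 and 22.7 ± 4.08, and the neutrophil chemokine gene Cxcl5 at 20.3 ± 7.88 and 5.63 ± 2.47. The log2 fold changes of Vcam1, Icam1, Selplg and Cxcl5 were −1.20, −0.93, −1.15 and −1.68, each with an adjusted p of 0.107 over all genes by limma. Of 22 list members tested, 16 (Ccl2 and Ccl7 included) were lower and 0 higher when adjusted over the list alone, and 0 passed over all genes. The groups were fully apart, with the knockout lower, for 15 of the 22, and for 2029 of all 14298 genes. Chance separates 10% of independent genes in both directions together. The list median was −1.06 and camera called it lower (adjusted p = 3.01e-11), against an adjusted p = 0.518 with an estimated correlation. The mean of the list per library was lower in all 3 knockout libraries (difference −1.03, exact two-sided permutation p = 0.1, the smallest possible). Without knockout S598 and S599, the libraries with the most thymocyte transcripts, S595 is the 1 knockout library left, and the median against the controls was −0.95.

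NF-kappaB targets, a list that shares 5 of its 22 members with other lists, were lower too, with Ccl2 and Icam1 at the smallest p. When adjusted over the list alone 17 were lower and 0 higher, and 0 passed over all genes. The median was −0.63 (camera adjusted p = 3.01e-11, and adjusted p = 0.518 with an estimated correlation). Interferon response genes stood lower by a smaller amount. The antiviral gene Bst2 stood at 63.8 ± 4.64 and 38.5 ± 4.82, and the chaperone gene Rtp4 at 26.0 ± 5.12 and 11.6 ± 1.38. Of 24 members 16 were lower and 0 higher when adjusted over the list alone, with 0 over all genes. The median was −0.53 (camera adjusted p = 1.18e-10, and adjusted p = 0.518 with an estimated correlation). It was the 1 list that limma's fry test, which asks whether the members move one way on balance, also called (adjusted p = 0.0463).

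Macrophage markers were lower as well. Itgam, the integrin chain of myeloid cells, stood at 159 ± 63.2 in the control and 49.8 ± 5.06 in the knockout arches, a 3.18-fold difference, and the signalling adaptor gene Tyrobp at 160 ± 24.3 and 75.1 ± 20.9, a 2.14-fold difference. Of 23 markers 19 were lower and 0 higher when adjusted over the list alone, with 0 over all genes, and the median was −0.999 (camera adjusted p = 4.66e-11, and adjusted p = 0.518 with an estimated correlation). Foam cell and lipid loading genes had a median of −1.10. Spp1, the osteopontin gene, stood at 5826 ± 2912 and 1118 ± 213, a 5.21-fold difference, and the fatty acid carrier gene Fabp5 at 432 ± 80.4 and 190 ± 62.0. When adjusted over the list alone 14 of 18 were lower and 0 higher, with 0 over all genes (camera adjusted p = 2.84e-08, and adjusted p = 0.518 with an estimated correlation). Antigen presentation genes of MHC class II, whose family members share similar sequence, had a median of −0.69. The cathepsin gene Ctss stood at 1572 ± 466 and 622 ± 293, and the invariant chain gene Cd74 at 904 ± 258 and 502 ± 111. When adjusted over the list alone 7 of 12 were lower and 0 higher, with 0 over all genes (camera adjusted p = 5.81e-04, and adjusted p = 0.590 with an estimated correlation). For the macrophage and foam cell lists the knockout library nearest the controls was S599, with list means of −0.07 and −0.05 about the mean of all libraries, against −0.87 and −0.95 in S598.

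**Figure D2:**
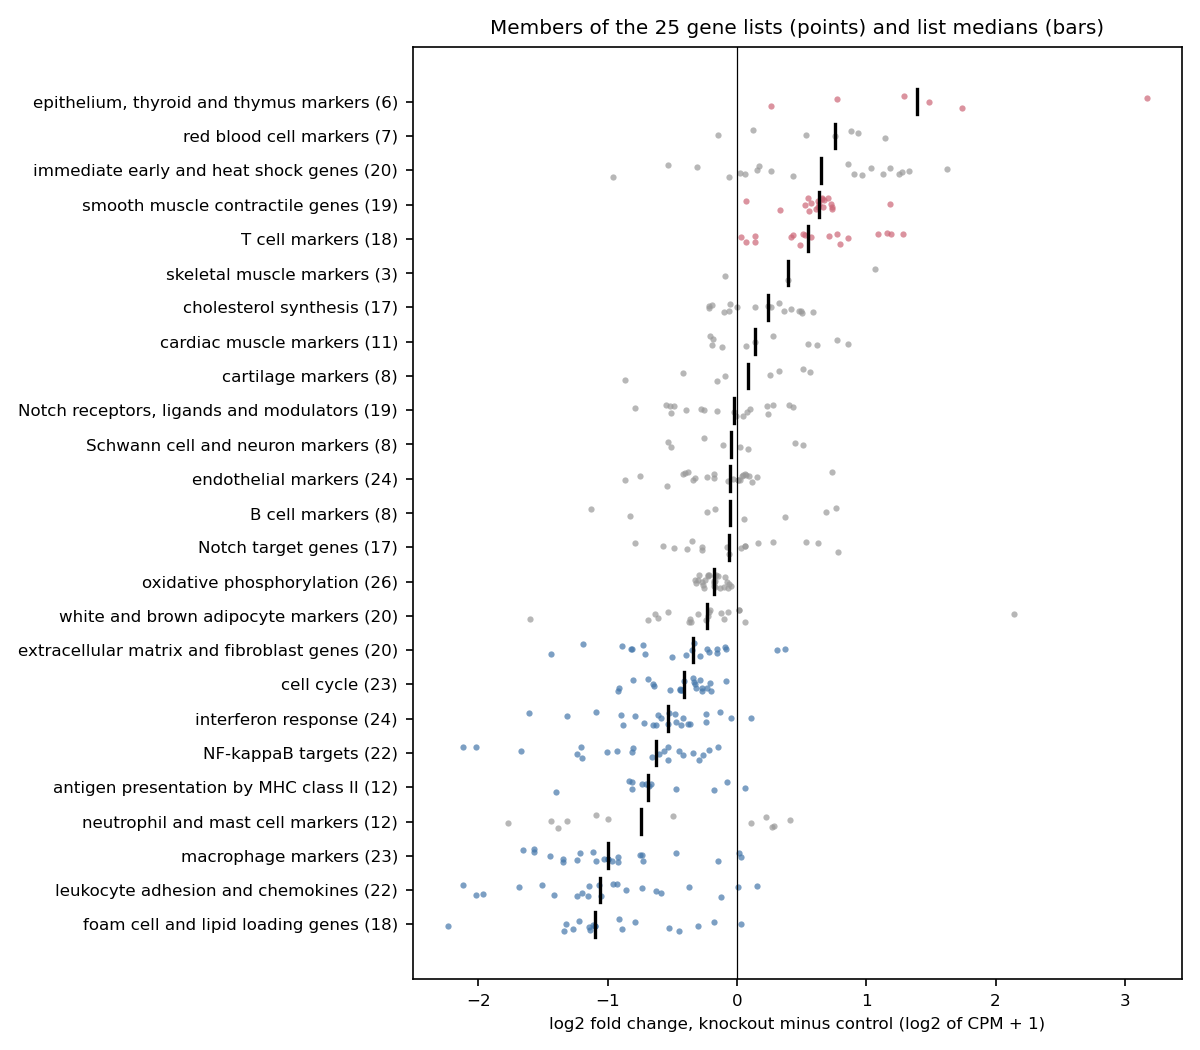
Log2 fold change, knockout minus control (horizontal axis, log2 of CPM + 1), of each tested member (points) of the 25 gene lists, with black bars at the list medians and the number tested in brackets. Lists that camera called are blue where lower and red where higher, and those it did not call are grey. The medians run from −1.10 for foam cell genes to 1.39 for epithelium, thyroid and thymus markers.

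Smooth muscle contractile genes stood higher in the knockout arches. The leiomodin gene Lmod1 stood at 416 ± 118 and 647 ± 58.6, a 1.56-fold difference, and the peptide receptor component Ramp1 at 48.5 ± 12.5 and 79.8 ± 9.23, a 1.64-fold difference. All 19 members had positive log2 fold changes, with a median of 0.63, yet 0 passed when adjusted over the list alone or over all genes. Camera called the list higher (adjusted p = 9.36e-08), against an adjusted p = 0.590 with an estimated correlation. Its mean per library did not separate the groups (exact permutation p = 0.2), since control S591 and knockout S599 stood at 0.04 and 0.02 about the mean of all libraries. Extracellular matrix and fibroblast genes stood lower. The matrix proteoglycan gene Lum stood at 1678 ± 643 and 601 ± 151, and the fibulin gene Fbln2 at 325 ± 75.7 and 181 ± 29.6. When adjusted over the list alone, 2 of 20 (Lum and Fbln2) were lower and 0 higher, with 0 over all genes, and the median was −0.34 (camera adjusted p = 9.58e-04, and adjusted p = 0.643 with an estimated correlation). With S595 as the 1 knockout library, assumed to vary like the controls, this call was lost (median −0.21, adjusted p = 0.254).

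Endothelial markers as a list did not move one way. Nos3, the endothelial nitric oxide synthase gene, stood at 46.3 ± 1.22 in the control and 25.4 ± 5.66 in the knockout arches (log2 fold change −0.86, adjusted p = 0.107), and the diaphragm protein gene Plvap at 84.8 ± 21.7 and 49.4 ± 9.01. Nos3 was the 1 of 24 members that was lower when adjusted over the list alone, with 0 over all genes. The list median was −0.05 and camera did not call it (adjusted p = 0.220). The median was 0.06 without knockout S595, and without knockout S599 it was −0.26 and the list was called (adjusted p = 2.39e-04).

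Markers of lymphoid tissue stood apart in 2 of the 3 knockout libraries. Dntt, a polymerase gene of immature lymphocytes, read 1.29 in knockout S595, 23.5 in S598 and 7.16 in S599, against 1.33 ± 0.417 in the controls. The T cell kinase gene Lck stood at 2.96 ± 0.30 in the control and 13.0 ± 14.1 in the knockout arches, and the costimulatory receptor gene Cd28 at 4.40 ± 1.39 and 8.24 ± 2.33. All 18 T cell markers had positive log2 fold changes, but 0 passed when adjusted over the list alone or over all genes. The list median was 0.55 (camera adjusted p = 0.00323, and adjusted p = 0.738 with an estimated correlation). That call was lost without S598 (median 0.10, adjusted p = 0.411), the median was 1.05 without S595, and the median in S595 alone against the controls was −0.48. Epithelium, thyroid and thymus markers had a median of 1.39 over 6 tested members (camera adjusted p = 0.00142, and adjusted p = 0.518 with an estimated correlation), 0.50 without S598, 2.25 without S595, and −0.03 with no call in S595 alone (adjusted p = 0.389). Scgb1a1 was the 1 member higher when adjusted over the list alone and also over all genes.

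B cell markers were not called (8 tested, median −0.06, camera adjusted p = 0.769). Cd72 stood at 41.4 ± 17.2 and 17.2 ± 2.07, and Cd22 at 37.4 ± 6.26 and 21.6 ± 8.56, and Cd72 alone was lower when adjusted over the list alone, with 0 over all genes. The median was −0.72 in S595 alone against the controls, 0.08 without S592 and 0.20 without S595. Red blood cell markers were not called either (7 tested, median 0.76, adjusted p = 0.220). The globin gene Hbb-bt, whose near-identical copies make its reads uncertain, stood at 33.5 ± 8.73 and 87.1 ± 68.5. The red blood cell list had a median of −1.40 in S595 alone against the controls, was called higher without S595 (median 1.83, adjusted p = 8.72e-07), and had a median of 0.08 without S599 (adjusted p = 0.939). Neutrophil and mast cell markers had a median of −0.74 over 12 members (adjusted p = 0.160), with the lipocalin gene Lcn2 at 190 ± 77.8 and 59.6 ± 42.4 and the chemokine receptor gene Cxcr2 at 4.38 ± 2.76 and 0.988 ± 0.773. That list was called lower without S599 (median −1.05, adjusted p = 0.0376), and its median was −0.45 without S594 and −0.48 without S595 with no call (adjusted p = 0.400 and 0.227).

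Markers of adipose tissue differed widely between libraries of one group. White and brown adipocyte markers had a list mean of 1.05 in control S591 and −0.76 in control S592 about the mean of all libraries. Their median was −0.23 over 20 members (camera adjusted p = 0.388), 0.24 without S591, and −0.76 with a call without S592 (adjusted p = 1.92e-04). Lep, the leptin gene, stood at 5.16 ± 7.15 and 17.5 ± 8.03, and Elovl3, a fatty acid elongase gene of brown fat, at 5.79 ± 3.55 and 1.796 ± 2.73. Oxidative phosphorylation genes likewise had a list mean of 0.69 in S591, and all 26 had negative log2 fold changes with a median of −0.18 (adjusted p = 0.103). Sdhb, a subunit gene of succinate dehydrogenase, stood at 119 ± 45.1 and 95.01 ± 10.96. The median of that list was 0.10 without S591, and it was called lower without S592, S594 or S595 (medians −0.42, −0.27 and −0.25) and, at an adjusted p of 0.0499, after quantile normalisation.

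Cardiac muscle markers had a median of 0.14 over 11 members (camera adjusted p = 0.173). Ryr2, the cardiac calcium release channel gene, stood at 53.3 ± 13.3 and 96.2 ± 17.2 and was the 1 member higher when adjusted over the list alone, and Hrc stood at 3.66 ± 0.582 and 6.29 ± 1.85. This median was 0.65 with a call without S591 (adjusted p = 0.00523), and −0.01, −0.09 and −0.06 without S592, S594 or S595. Skeletal muscle markers had 3 tested members and a median of 0.40 (adjusted p = 0.0836). Casq1, a calcium store protein gene, stood at 22.8 ± 7.12 and 47.3 ± 3.05 and was higher when adjusted over the list alone, and Eno3 stood at 11.2 ± 2.31 and 14.97 ± 2.20. The skeletal list was called higher without S591 or S599 (adjusted p = 0.0327 and 0.0297), and its median was 0.29 without S592 or S598 with no call. Cartilage markers (8 tested, median 0.08, adjusted p = 0.667, and −0.03 without S591) included Cytl1 at 94.6 ± 33.0 and 130 ± 14.7 and Col2a1 at 7.63 ± 3.77 and 3.70 ± 1.91. Schwann cell and neuron markers had a median of −0.05 over 8 members, although camera placed them on the higher side (adjusted p = 0.955), and 0.09 and 0.0040 without S598 or S599. The myelin genes Mbp and Prx stood at 23.1 ± 2.57 and 16.0 ± 2.70, and at 10.5 ± 1.46 and 14.6 ± 0.601. Over all genes 0 members of these muscle, cartilage and nerve lists passed.

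**Figure D3:**
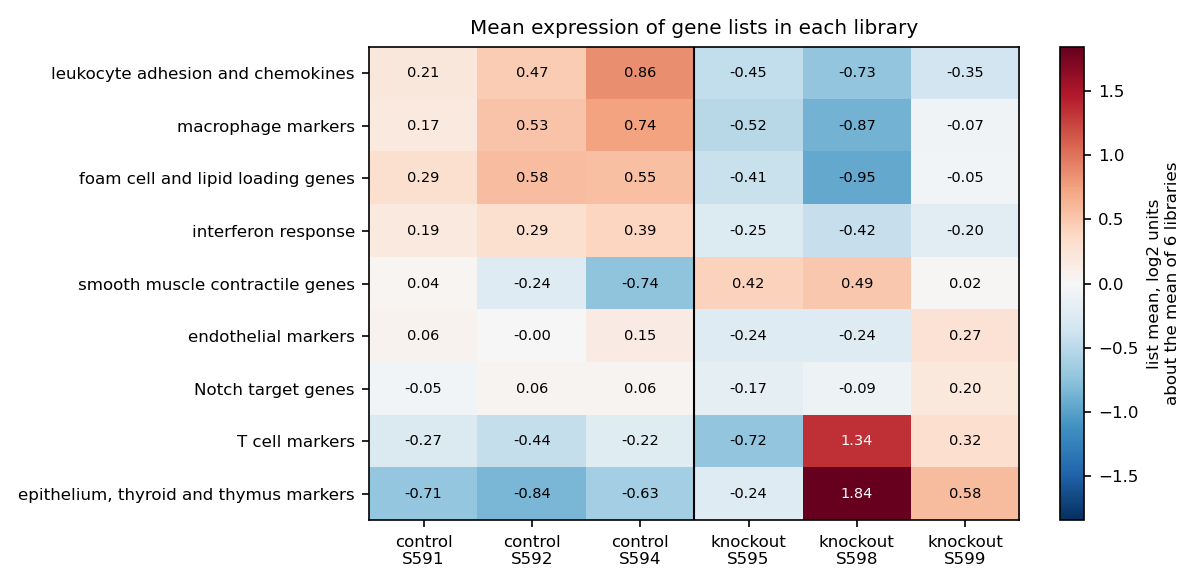
Mean of each of 9 gene lists (vertical axis) in each of the 6 libraries (horizontal axis), in log2 units about the mean of all libraries, red above and blue below, with a vertical line between control and knockout. Adhesion, macrophage, foam cell and interferon lists are above 0 in all 3 controls and below 0 in all 3 knockouts, and the T cell list stands at 1.34 in knockout S598 against −0.72 in S595.

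Proliferation genes stood lower in the knockout arches. The mitotic genes Cdc20 and Plk1 stood at 6.11 ± 3.46 and 2.51 ± 0.495, and at 5.60 ± 2.61 and 2.64 ± 0.761. All 23 cell cycle genes had negative log2 fold changes with a median of −0.41, but 0 passed when adjusted over the list alone or over all genes (camera adjusted p = 8.67e-04, and adjusted p = 0.738 with an estimated correlation). This call was lost without control S594 (median −0.11, adjusted p = 0.161) and at a minimum of 10 CPM (median −0.29, adjusted p = 0.105). Immediate early and heat shock genes, which respond to handling of tissue, had a median of 0.65 over 20 members (camera adjusted p = 0.0574). The phosphatase gene Dusp1 stood at 98.9 ± 18.8 and 246 ± 79.4 and was higher when adjusted over the list alone, and the transcription factor gene Junb stood at 46.1 ± 7.83 and 23.0 ± 1.26 and was lower, with 0 over all genes. The list was called higher without S592, S594 or S599 (adjusted p = 0.0149, 0.0166 and 3.24e-04), and its median was 0.14 without S591 and 0.19 without S595 with no call (adjusted p = 0.387 and 0.131). Cholesterol synthesis genes had a median of 0.24 over 17 members (adjusted p = 0.101), with Msmo1 at 23.5 ± 1.46 and 30.6 ± 3.69 and Lss at 17.7 ± 6.64 and 24.2 ± 3.45. That list was called higher without S591 or S599 (adjusted p = 0.00253 and 0.0194), its median was 0.07, 0.13 and 0.12 with no call without S592, S595 or S598, and 0 members passed when adjusted over the list alone or over all genes.

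Of the 25 lists tested, camera with its preset correlation called 8 lower and 3 higher. With an estimated correlation it called 0, with 1 list (interferon response) at an unadjusted p of 0.05, and fry called 1, with 6 at an unadjusted p of 0.05. The adjusted p of 0.518 repeated above is 1 value that the adjustment gave to several lists. Their unadjusted camera p with an estimated correlation ran from 0.0226 (interferon response) to 0.124 (foam cell genes).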

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

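The limma-voom test and the fit without knockout S598 and S599 were chosen only after the results were seen. The latter leaves S595 as the 1 knockout library, which is assumed to vary like the controls. No paired analysis was possible because the columns carry no replicate number. The count of 3 genes became 0 with a pseudocount of 0.1, 0 at a minimum of 10 CPM (10165 genes tested), 1 without the variance trend, 1011 with array weights, 0 with edgeR, 0 with limma-voom, 0 without S598 and S599 and 900 with DESeq2, which left 848 adjusted p undefined. Thresholds of 0.10 adjusted and 0.05 unadjusted gave 10 and 2860 genes. With 1 library left out it ran from 0 to 671. It was 3 or 4 with a pseudocount of 5, no filter (which removed nothing), TMM applied again, robust variances and quantile normalisation, and the 2 scalings moved the median of all genes by 0.00088 and 0.0466. Array weights gave S591 the lowest weight (0.570). The causes were not tested, except that leaving out libraries leaves fewer samples. The count of 11 lists became 0 with an estimated correlation and 1 with fry, and stayed between 8 and 16 under the other alternatives. The adhesion list kept its median of −1.06 by construction under an estimated correlation and fry while its call was lost (adjusted p = 0.518 and 0.0808, where all its alternatives ran from 5.74e-13 to 0.518), and with 1 library left out it ran from −1.26 to −0.86. With 1 library left out, the Rbpj log2 fold change ran from −0.045 to 0.12 and the Notch target median from −0.28 to 0.19. Medians that changed sign in that way ran from −0.26 to 0.063 for endothelial markers, −0.16 to 0.20 for B cells, −0.76 to 0.24 for adipocytes, −0.42 to 0.10 for oxidative phosphorylation, −0.093 to 0.65 for cardiac muscle, −0.031 to 0.16 for cartilage and −0.21 to 0.093 for Schwann cells. Log2 fold changes ran from −0.26 to 0.17 for Cdh5, −0.28 to 0.25 for Hes1 and −0.45 to 0.028 for Sdhb. Without S598 and S599 the sign also turned for Rbpj (−0.16), Cdh5 (−0.27), Hes1 (−0.30), Lck (−0.11), Hbb-bt (−1.02), Dntt (−0.00534), T cells (−0.48), adipocytes (0.092), Schwann cells (0.056), red blood cells (−1.40) and the epithelium, thyroid and thymus list (−0.027). Array weights turned B cells (0.027), adipocytes (0.065) and Cdh5 (−0.014), and quantile normalisation turned Notch receptors (0.021). Over 65 named genes, 1079 of the values under alternatives kept direction and side of the threshold, 29 lost the call, 102 gained one and 12 turned. Only the 3 genes called from all 6 libraries had a call to lose, so all 29 losses fell on them. Most of the 1079 kept values were genes without a call that stayed without one, which says little about how stable the calls were. Over 23 lists those numbers were 368, 23, 23 and 19. Depth limits genes such as Cyp2a5, with 0 or 1 read per control library.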

Other observations

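The gene groups and single genes below were chosen after the data were seen, as were the tests of time of day, glucocorticoids, tissue dilution and endothelial number; the airway test and the counts over other splits were set before their results were seen. Targets of interleukin-6 and STAT3 signalling formed a lower group. The 14 such genes, picked after the data were seen and with Socs3 and Il4ra among them, had a median log2 fold change of −1.36, so this is a description and no test. The receptor gene Osmr stood at 158 ± 26.2 in the control and 80.9 ± 16.7 in the knockout arches, the corepressor gene Sbno2 at 163 ± 36.9 and 62.4 ± 11.03, and Il6 itself at 7.80 ± 2.85 and 2.13 ± 1.161 (SD, n = 3 each). Stat3 stood at 274 ± 42.4 and 188 ± 20.2.

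Lysosomal genes stood lower alongside the foam cell genes, with a median of −0.82 over 12 genes picked in the same way. The groups were apart for 8 of the 12. About the mean of all libraries, their mean was −0.377 in knockout S595, −0.826 in S598 and 0.063 in S599. The controls S591, S592 and S594 stood at 0.109, 0.558 and 0.473. Npc2, a lysosomal cholesterol carrier gene, stood at 420 ± 32.6 and 239 ± 50.5, and the acid lipase gene Lipa at 391 ± 29.2 and 238 ± 107. Endoplasmic reticulum chaperones had a smaller median of −0.41 over 10 genes, and Sdf2l1 stood at 26.6 ± 2.05 and 12.0 ± 2.02. Thymocyte genes (Rag1, Dntt and Cd8b1) had a median of 1.49 that came from 2 libraries, since Rag1 read 2.51 in knockout S595, 47.9 in S598 and 12.8 in S599 against 3.88 ± 1.32 in the controls.

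The first pattern was the airway transcripts, since 7 airway secretory genes, Scgb3a2 and Sec14l3 among them, had fully separated groups and a median log2 fold change of 2.13. Airway tissue left on the knockout dissections is a candidate explanation. Of 16 further airway secretory markers 7 were not among the genes listed, which all exceed 1 CPM in at least 3 libraries. The other 9 had a median of 0.33 with a standard error of 0.15, taken over those 9 genes and not over libraries. The median lay between what airway tissue would need (above 0.5) and what would argue against it (below 0 by more than the standard error). Cbr2, at 243 ± 27.1 and 302 ± 53.8, has a baseline in the arch that would hide a small share of airway tissue, but the low markers Cldn10 (1.68 ± 0.127 and 1.28 ± 0.294) and Muc1 (3.32 ± 0.938 and 2.35 ± 0.489) had lower means in the knockout, with overlapping groups. Airway tissue and a difference due to the genotype cannot be told apart here.

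The second pattern was the circadian clock. The 10 clock genes in phase with Dbp had a median of 1.14, and Dbp read 18.6, 7.71 and 38.5 in the controls and 112, 57.1 and 85.6 in the knockouts. Of 5 genes in antiphase 0 passed when adjusted over the list alone. Beside Arntl (29.4 ± 11.9 and 16.5 ± 6.21) and Npas2, the other 3 (Clock, Nfil3 and Cry1) had a median of −0.28. Its standard error of 0.195 was taken over those 3 genes, not over libraries, and does not measure the uncertainty of the group difference. Collection at different times of day would need a median below −0.3 by more than that standard error. A median above 0 by more than it would argue against that cause. The observed median met neither condition. Time of day and an effect of the genotype thus cannot be told apart here, and collection times are not given in the sources used here. Glucocorticoid release before collection stays open too. The 10 glucocorticoid targets had a median of −0.20 with an SD of 0.779, and their mean was −0.28 with a standard error of 0.246 over the 10 genes. The SD describes single members rather than the uncertainty of their median, so the test could hardly decide either way. They went both ways, with 3 of 10 positive, Klf9 at 78.4 ± 4.12 and 123 ± 17.3 and Mt2 at 174 ± 85.2 and 54.3 ± 38.4.

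The third pattern was the lower adhesion, macrophage and interferon lists with higher smooth muscle genes. Dilution of the wall by tissue without smooth muscle, such as thymus or fat, would lower both. The smooth muscle list was 0.62 higher per library with a standard error of 0.271. That rise was already part of the pattern, and the list mean did not separate the groups (exact two-sided permutation p = 0.2). The adhesion list mean changed by −1.03, and dilution as the whole cause would have lowered the smooth muscle list too. These values argue against dilution as the whole cause for these lists. Because the rise had been seen before, this describes the values and is no independent test. Dilution as a part of the cause stays open. Fewer endothelial cells as the whole cause of the lower adhesion genes would lower the endothelial list by at least as much. The endothelial list mean less the adhesion list mean per library was 0.89 higher in the knockout, with a standard error of 0.204 over libraries. These values argue against that cause for the adhesion list as a whole. Both lists had been seen before this comparison was written, so it describes the values and is no independent test. Whether fewer macrophages account for the lower adhesion genes was not tested and stays open. A smaller or less inflamed lesion, through the genotype or through chance differences between the animals or dissections, may account for the pattern and stays open.

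Other splits of the 6 libraries were counted as well. There are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3 genes at an adjusted p of 0.05, where 2 of the 10 splits gave as many and the highest other gave 9 (S591, S592 and S595 against the rest, with 287 genes at an unadjusted p of 0.05). At an unadjusted p of 0.05 the real split gave 2860 genes and the highest other 1391, so 1 split gave as many. Of the gene lists the real split gave 11 and the highest other 18, and 6 splits gave as many.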
